A study of Mus musculus with 6 samples.

How the data were processed

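Gene expression was measured on 6 Illumina mouse bead arrays, each hybridised with biotin-labelled total RNA from mouse brain tumour tissue. Per the labels' protocols, the tumours were gliomas made with the RCAS/tva system, in which an avian retrovirus infects only cells that carry the tva receptor from a transgene. Chicken fibroblasts producing virus for PDGFB were injected into the right frontal cortex together with fibroblasts producing virus for either HoxA5 or the fluorescent protein mCherry. The samples were grouped by their titles into HoxA5 tumours (n = 2) and mCherry tumours (n = 4), the control group. The mice carried either 1 or no intact copy of Ink4a/Arf on a mixed strain background, and the genotype of each mouse is not given in the sources used here. Nothing in the labels says that each tumour came from a separate mouse, so p-values measure only the spread between these samples.

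The table used for the main results holds 45281 probes, and the authors deposited its intensities without normalization between arrays, per the file name. Each intensity is 1 value per probe and array on a linear scale, and the lowest on any array was 102.5, so no background had been subtracted to 0. The authors deposited a detection p-value beside each intensity, per the file headers. These p-values move in steps of 0.00106, as ranks against a fixed number of negative control probes would. A second table holds the authors' processed log2 values for the same probes. The submitters' processing notes name limma for it, without a version or a step. Its columns rank the probes as the scanner intensities do (Spearman correlation across probes of 1 on every array), have medians of 7.29 and run from 6.83 to 15.03. They differ from log2 of quantile-normalized intensities without background correction by at most 0.135 (median 0.0489). The scale is therefore taken as log2, without centring of genes, while the background step and offset remain unknown.

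Intensities were background-corrected, quantile-normalized and put on the log2 scale with neqc in limma 3.58.1 under R 4.3.3. This function fits a normal-exponential background, here with negative controls inferred from the detection p-values, and adds an offset of 16. The offset pulls differences of dim probes towards 0, so that a fold of a dim gene is understated. Quantile normalization gives every array the same distribution of values. It can therefore hide a difference in total RNA or spread a large 1-sided change over other genes. Of the probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none. Of the single symbols, 34807 were found in the GRCm38.p6 gene table, which was used for names only, and 0 were changed by it. The array files name no genome build, so no coordinates are given.

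A probe was kept where it had 1 symbol and a detection p-value under 0.05 on at least 2 of the 6 arrays, which 19479 probes met. Each of the 12242 genes tested was represented by its brightest probe, by mean over all arrays. Of the 4858 genes with 2 or more detected probes, all probes of 3448 moved in the same direction. HoxA5 and mCherry tumours were compared with limma's lmFit and eBayes with an intensity trend, with 4 residual and a median of 5.52 prior degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and this is the adjusted p given for single genes throughout. For a gene not above background on any array of a group, the fold is given as a bound. The brighter group's mean is then set against the mean over the dimmer group's arrays of the higher of that array's lowest detected signal and the gene's own value. For single values an exact two-sided permutation test over the 15 splits of the arrays was used, whose smallest p is 0.0667.

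The 30 gene lists were fixed before the data were examined, together with the design, the rule for named genes and all alternatives except those said below to be added. The 26 lists with at least 4 measured genes were tested with camera, using a preset correlation between genes of 0.01 and adjustment over the lists. Adjusted p-values with an estimated correlation, and from fry, which tests whether a list's genes move on balance in 1 direction, were computed beside them. Named genes are Hoxa5, Pdgfb and Cdkn2a whatever their values, the 12 largest log2 differences in each direction among called genes whose arrays do not overlap between groups, and up to 4 members of each list by smallest p. Predicted genes without a name were passed over. Sex was read from Xist and Eif2s3y on each array.

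The alternatives were no background correction, scaling to the same median in place of quantiles, and the authors' values. They were also other detection filters, other ways of joining probes, other variance models, array weights, the replicate number as a block, other thresholds, and leaving out each array. Sex as a block and the mean of the neuron list as a covariate were added after the data had been seen. A block for the chip was not run, because the files name no chips. Figures were drawn with matplotlib 3.10.9.

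The median intensity per array ran from 136.1 to 166.8 and the number of detected probes from 19950 to 21904. The number of arrays limits the precision. On simulated data with the real genes and spreads, 2.99% of genes changed by a log2 difference of 1 were called. Of those changed by 2, 56.7% were called, and of those changed by 3, 81.8%, with 6 false among 100 calls. This was 1 draw, in which 67, 67 and 66 of 12242 genes were changed by 1, 2 and 3. In the real data 3014 genes had an unadjusted p under 0.05 in limma. Recovery after Benjamini-Hochberg adjustment depends on the share of changed genes, so these rates need not hold for the real comparison. In 20 draws with 1 list shifted by 1 on the log2 scale, camera called that list in 20, and 2 of 500 tests of unshifted lists were called. Genes were drawn independently of each other in these simulations. They therefore do not show how often correlation between the genes of a list leads to a false call.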

Results

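The transcriptomes of 6 mouse gliomas were measured on bead arrays, 2 from tumours induced with HoxA5 virus and 4 from tumours induced with mCherry virus. Both kinds were driven by PDGFB. The question addressed was whether raised expression of Hoxa5, a homeobox transcription factor of the Hoxa cluster, affects how aggressive such tumours are. The HoxA5 arrays had median intensities of 153.1 and 166.8 and detected 20097 and 20970 probes. The mCherry arrays had medians of 156.9, 152.4, 136.1 and 141.3 and detected 20343, 21904, 21471 and 19950 probes. By Xist and Eif2s3y, HoxA5 1, mCherry 1 and mCherry 2 came from males, and HoxA5 2, mCherry 3 and mCherry 4 from females. Across genes, the HoxA5 arrays correlated with each other at r = 0.968. The mCherry 4 array correlated with them at 0.963 and 0.962, and with the other mCherry arrays at 0.921 to 0.957. Genes are not independent replicates, and these correlations describe the arrays only.

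The array's Hoxa5 probe gave no signal above background on any tumour. Its detection p-values ran from 0.0652 to 0.771, and it was detected on 0 of 6 arrays. Its normalized log2 intensity was 4.51 ± 0.0325 (SD, n = 2) in HoxA5 tumours and 4.70 ± 0.305 (SD, n = 4) in mCherry tumours, a difference of -0.18 (exact permutation p = 0.667, two-sided). Which part of the transcript the probe covers and which the virus carries are not known here, so the probe does not check the delivered gene. Pdgfb, whose gene product drove both kinds of tumour, was at 9.48 ± 0.146 (SD, n = 2) and 9.16 ± 0.724 (SD, n = 4), with a difference of 0.32 (limma adjusted p = 0.684). These are values of its brighter probe, and its other probe was detected on 0 arrays. Whether the brighter probe sees the PDGFB delivered by the virus is not known here, so it does not compare the driver between the groups. Cdkn2a, the Ink4a/Arf locus, was at 8.85 ± 0.0299 (SD, n = 2) and 7.63 ± 1.08 (SD, n = 4), a difference of 1.22 (limma adjusted p = 0.242), by the brightest of 3 probes. That probe and a second, with a difference of 0.72, were detected on all 6 arrays and the third on 0. Neither difference passed the threshold. That of Cdkn2a was -1.65 with the neuron list mean as a covariate, a setting added after the data were seen.

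HoxA5 tumours had lower levels of many neuronal, myelin and choroid plexus genes and higher levels of genes of the extracellular matrix and of cell division. Ttr, the thyroxine carrier made by the choroid plexus, fell by 8.37 on the log2 scale (SE 0.443, adjusted p = 8.83e-05), from 14.47 ± 0.305 (SD, n = 4) to 6.10 ± 1.32 (SD, n = 2), and was detected on 1 of the 2 HoxA5 arrays. Aldh1a3, an enzyme of retinoic acid synthesis, rose by 4.03 (SE 0.887, adjusted p = 0.0322), from 6.72 ± 1.72 (SD, n = 4) to 10.75 ± 0.258 (SD, n = 2). In all, 148 genes were higher and 568 lower in HoxA5 tumours, and 3014 genes had an unadjusted p under 0.05 in limma. The 2 HoxA5 arrays lay outside the range of the mCherry arrays for all 716 called genes and for 35.5% of all genes, against 13.3% by chance.

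The balance of calls moved with the background correction and the scaling, and their number with single arrays. Of the calls, 20.7% were higher in HoxA5 tumours, against 31.2% (158 higher, 349 lower) without background correction and 37.7% (265 higher, 437 lower) with median scaling, which moved the median difference of all genes from 0.072 to 0.20. Numbers of higher and lower genes were 3 (Adgra3, Atp10b and Cryl1) and 116 without HoxA5 1, 0 and 2 without HoxA5 2, 8 and 163 without mCherry 1, 18 and 229 without mCherry 2, 96 and 426 without mCherry 3, and 1038 and 1370 without mCherry 4. At an unadjusted p under 0.05, 813 genes were higher in limma without HoxA5 2. With sex as a block, added after the data were seen, 31 and 307 genes passed. Lamp5 and Ttr were the only genes that passed in every fit with 1 array left out. The other 3 genes named in this paragraph were chosen after their values were seen.

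Of the 12 largest higher differences, 2 belonged to genes of the fibroblast and collagen matrix list, Lum and Col1a1. Lum, a collagen-binding proteoglycan, rose 8.93-fold, Col1a1, a chain of type I collagen, 6.93-fold, and the metalloproteinases Mmp3 and Mmp13 8.58-fold and 7.90-fold. Timp1, an inhibitor of metalloproteinases, rose 8.05-fold and the acute phase gene Saa3 6.52-fold. The HoxA5 1 array carried much of 3 of these, with Col1a1 at 9.85 and 7.58 on the HoxA5 arrays (SD 1.60), Mmp3 at 10.27 and 8.02 (SD 1.59) and Saa3 at 9.18 and 7.45 (SD 1.22). Without HoxA5 1 they were at 3.14-fold, 3.92-fold and 3.57-fold. Of the 12 genes, 11 were tested without that array. That fit has 1 HoxA5 array, so its folds are sizes only and do not show that a call was kept. Timp1 was then at 5.59-fold, Mmp13 at 6.02-fold, Lum at 8.67-fold and Aldh1a3 at 18.7-fold. Bub1b was at 8.09-fold, Kif11 at 7.11-fold, Aurka at 6.99-fold and Tecta at 9.57-fold. Lrrc15, a membrane protein of activated fibroblasts, was not above background on any mCherry array and was at least 8.16-fold higher (adjusted p = 0.0114), with 8.14 ± 1.71 (SD, n = 2) in HoxA5 tumours. From HoxA5 1 alone (9.35) that bound is 18.8-fold and from HoxA5 2 alone (6.94) 3.53-fold, and without HoxA5 1 the gene did not meet the detection filter. Bub1b, Kif11 and Aurka, which act at the mitotic spindle, rose 8.07-fold, 7.10-fold and 6.68-fold, and Tecta rose 7.32-fold. The adjusted p-values of these 11 genes and Aldh1a3 ran from 0.00921 to 0.0484. With the neuron list mean as a covariate, the differences of Aldh1a3, Bub1b, Tecta, Kif11 and Aurka were negative. Of 52 called genes that are named here, 23 had log2 differences over 1.5 times smaller without background correction, and 7 no longer passed.

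Of the 11 largest lower differences after Ttr, 1 belonged to a gene of the neuron list. This was Slc17a6, a vesicular glutamate transporter, which fell by 4.98 on the log2 scale (31.6-fold). Cpne9 fell by 4.90, Scn4b, a sodium channel subunit, by 4.68 and the calcium sensor Hpca by 4.56. The log2 difference was -4.52 for Tac1, the precursor of substance P, -4.34 for Lamp5, -4.31 for Pvalb, a calcium buffer of interneurons, and -4.21 for Vsnl1. It was -4.13 for Slc30a3, a synaptic zinc transporter, and -4.12 for Lin7b. Ptgds, a prostaglandin synthase of meninges, choroid plexus and oligodendrocytes, fell by 4.16. Their adjusted p-values ran from 0.00154 to 0.0440, and Cpne9 and Scn4b were each detected on 1 of the 2 HoxA5 arrays. With the neuron list mean as a covariate the differences of Scn4b and Tac1 were positive.

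**Figure D1:**
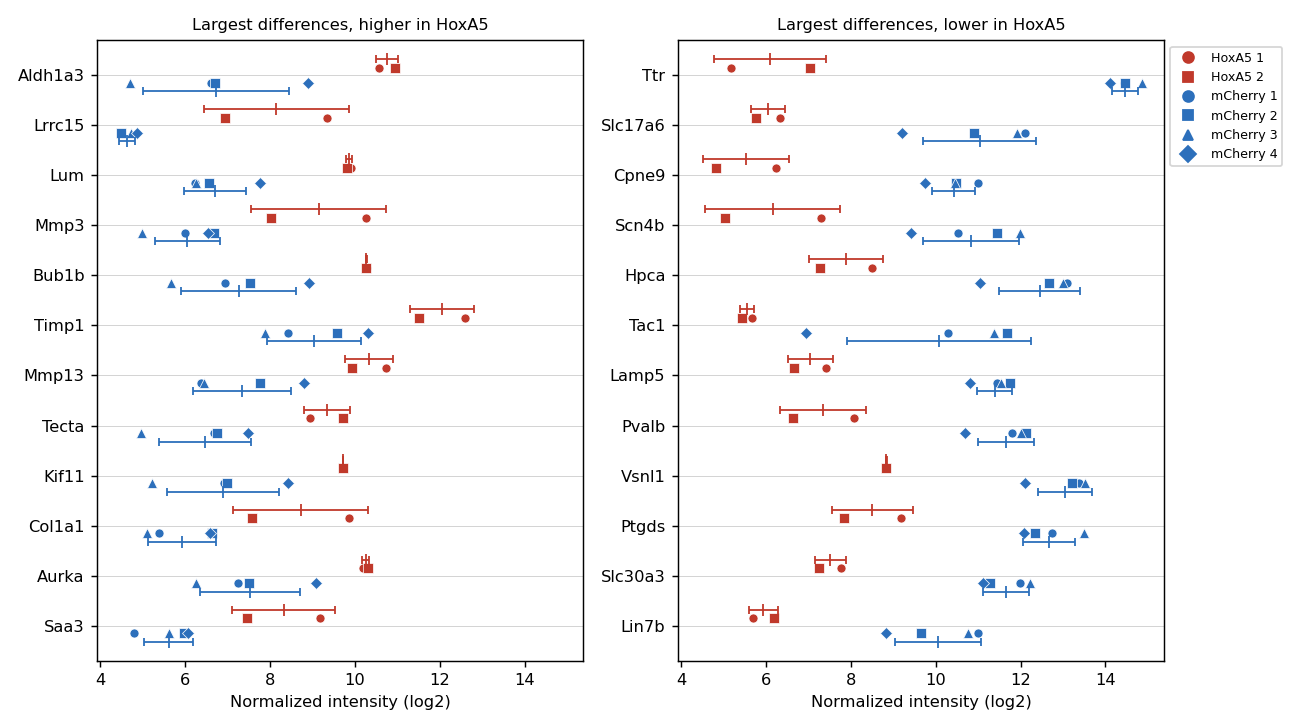
Normalized log2 intensity (horizontal axes) of the 12 genes with the largest called difference in each direction, 1 point per array, red for HoxA5 and blue for mCherry tumours; bars above and below the points give the mean and SD of each group (n = 2 and n = 4). Only genes with both HoxA5 points beyond all 4 mCherry points were eligible, so that separation was a condition of the choice. For most genes mCherry 4 is the mCherry array nearest to the HoxA5 points.

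All 11 measured genes of the neuron list fell, and all 11 also passed when adjusted over the list alone. Rbfox3, the neuronal nuclear antigen NeuN, fell by 3.74 (SE 0.443, adjusted p = 0.00571), Syt1, a calcium sensor of synaptic vesicles, fell by 3.29, and the kinase Camk2a fell by 3.51. The list mean was 8.97 and 8.02 on the HoxA5 arrays, 11.80, 11.87 and 12.29 on mCherry 1 to 3, and 10.53 on mCherry 4. The list's median difference was -3.29 (camera adjusted p = 2.75e-11; adjusted p = 0.499 with an estimated correlation and 0.0472 in fry).

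Myelin genes fell with them, 7 of 11 members over all genes and 7 adjusted over the list alone. Mog fell by 3.62, Opalin by 3.16, Mal by 3.08 and Mag by 2.39, all of them products of myelinating oligodendrocytes, with adjusted p-values from 0.00571 to 0.0115. The list median was -2.12 (camera adjusted p = 6.38e-07; adjusted p = 0.499 with an estimated correlation and 0.0386 in fry). Of the 6 ependymal and choroid plexus genes 3 fell, 4 when adjusted over the list alone. Besides Ttr these were Clic6, which fell by 3.65, and Kl, which was not above background on any HoxA5 array and at least 4.95-fold lower (adjusted p = 0.0402). Folr1 was at least 2.79-fold lower without passing (adjusted p = 0.0971). The other 2 members went the other way without passing, Aqp1 at 1.08 and Foxj1 at 0.24, and are named after their values were seen. That list's median was -2.45 (camera adjusted p = 0.00285; adjusted p = 0.499 with an estimated correlation and 0.0386 in fry), and it was -0.92 without background correction and -1.02 in the authors' values. The myelin median was -0.97 without a detection filter, -1.36 with the mean of a gene's probes and -1.40 without HoxA5 2. With the neuron list mean as a covariate, which is the neuron list's own mean, none of these 3 lists passed.

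Of 12 astrocyte genes 2 fell, and 5 when adjusted over the list alone. The connexin Gjb6 fell by 2.90 (SE 0.494, adjusted p = 0.0133) and the connexin Gja1 fell by 1.28 (adjusted p = 0.0373), while Aldoc differed by -0.90 and Slc1a2, whose probes disagreed in direction, by -0.93. The median was -0.73 (camera adjusted p = 0.0112, and 0.499 with an estimated correlation), and -0.76 without HoxA5 2.

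Genes of mitosis rose, 7 of 20 measured members over all genes and 19 adjusted over the list alone. Besides Bub1b, Kif11 and Aurka these were Cenpf, a kinetochore protein, 3.35-fold, and Ttk, Ube2c and Ccna2. None of these last 3 was above background on an mCherry array, and they were at least 1.92-fold, 1.76-fold and 1.76-fold higher. The list mean was 9.42 and 9.64 on the HoxA5 arrays, and 7.40, 7.55, 6.23 and 8.56 on mCherry 1 to 4. Its median difference was 2.30 (camera adjusted p = 2.77e-10; adjusted p = 0.499 with an estimated correlation). Of 24 DNA replication genes only Pcna, the sliding clamp of DNA polymerases, rose over all genes, 3.83-fold (adjusted p = 0.0439), and 19 rose when adjusted over the list alone. Fen1 differed by 1.12, Rrm1 by 1.89 and Pole by 2.03. This list's median was 1.80 (camera adjusted p = 3.41e-08; adjusted p = 0.499 with an estimated correlation). Both lists were highest in the tumours with the lowest neuron list means, and with that mean as a covariate their medians were -1.15 and -1.80.

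None of 15 DNA repair genes passed over all genes and 9 rose when adjusted over the list alone. Fanci differed by 1.28, Fancd2 by 1.13, Mgmt by 1.07 and Brca2 by 0.94, and the median was 0.94 (camera adjusted p = 1.52e-04, and 0.499 with an estimated correlation). That median was 0.39 without background correction and 0.45 in the authors' values, where the list passed. In limma, 10 of the repair genes had an unadjusted p under 0.05. Of 15 p53 target genes Phlda3 alone rose, 2.34-fold (adjusted p = 0.0498), also when adjusted over the list alone. Sesn2 differed by 0.91, Zmat3 by 0.54 and Sesn1 by -0.60, and the list did not pass (median 0.44, camera adjusted p = 0.0918). It passed without HoxA5 1 (adjusted p = 0.0261), without mCherry 2 (0.0245), without a detection filter (0.0449), with the mean of a gene's probes (0.0476) and with every probe on its own (0.0177).

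Of 10 fibroblast and collagen matrix genes 4 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone. Dcn, a small proteoglycan, rose by 1.91 (SE 0.286, adjusted p = 0.00948) beside Lum and the type I collagen chains. Igf2, a growth factor expressed in meninges and choroid plexus, fell by 3.18 (adjusted p = 0.0125). The list mean was 10.20 on HoxA5 1 and 8.86 on HoxA5 2, against 7.41, 8.12, 7.97 and 8.51 on mCherry 1 to 4. Its median difference was 2.01 (camera adjusted p = 8.09e-04; adjusted p = 0.499 with an estimated correlation).

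Snai1, a repressor of E-cadherin, was the member of the transition and invasion list that rose, 3.20-fold (adjusted p = 0.0485), with 2 of 12 genes passing when adjusted over the list alone. Mmp14 differed by 1.78, Itga5 by 1.79 and Twist1 by 1.26, and the median was 1.46 (camera adjusted p = 6.21e-04; adjusted p = 0.499 with an estimated correlation). It was 0.90 without HoxA5 1 and 0.91 without background correction, where the list passed, and 0.054 with the neuron list mean as a covariate, where it did not (adjusted p = 0.665). In the mesenchymal glioblastoma list Timp1 rose among 17 genes and 3 passed when adjusted over the list alone. Cd44 differed by 2.06, Runx1 by 1.39 and Lgals3 by 1.14 (median 1.04, camera adjusted p = 1.69e-03, and 0.576 with an estimated correlation). The mesenchymal median was 0.45 without background correction and 0.51 in the authors' values, where the list passed. With the neuron list mean as a covariate it was -0.78, and the list did not pass. None of the 16 proneural and oligodendrocyte progenitor genes passed in limma over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. Sox4 differed by 1.89, Lhfpl3 by 1.43, Sox11 by 1.05 and Dll3 by 0.73. That list's median was 0.79 (camera adjusted p = 7.01e-03; adjusted p = 0.673 with an estimated correlation), 0.52 without mCherry 3 and -1.26 with the neuron list mean as a covariate.

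Among immune genes, 2 of 10 type I interferon response genes rose, and 4 when adjusted over the list alone. These were Rsad2, an antiviral enzyme, 2.74-fold (adjusted p = 0.0351), and Usp18, 2.42-fold (adjusted p = 0.0417), while Irf7 differed by 1.25 and Oasl2 by 0.81. The median was 0.86 (camera adjusted p = 4.84e-03; adjusted p = 0.499 with an estimated correlation and 0.0386 in fry), and 0.43 without a detection filter. None of 10 monocyte and neutrophil genes passed in limma over all genes, with 5 at an unadjusted p under 0.05, and 3 rose when adjusted over the list alone. Arg1 differed by 2.70, Vcan by 2.51, Plac8 by 1.24 and S100a8 by 1.22 (median 0.94, camera adjusted p = 0.0121; adjusted p = 0.542 with an estimated correlation). No antigen presentation gene passed in limma among 14, over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05. Cd74 differed by -1.78, H2-Eb1 by -1.36, H2-Aa by -1.13 and H2-D1 by -0.71. The median was -0.42 (camera adjusted p = 0.0425, and 0.673 with an estimated correlation), -0.22 without HoxA5 1 and -0.81 without HoxA5 2. Without mCherry 2, 3 and 4 it was -0.44, -0.40 and -0.42, and the list did not pass (camera adjusted p = 0.119, 0.108 and 0.103). Nor did it with median scaling (0.0597) or array weights (0.0606).

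The microglia and macrophage list did not pass (median 0.18, camera adjusted p = 0.528) and none of its 11 genes did in limma, over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05. Tmem119 differed by 0.58, P2ry12 by -0.39, C1qb by 0.23 and C1qc by 0.20. The T and NK cell list did not pass (median -0.40, camera adjusted p = 0.444). In limma 0 of its 7 genes passed, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. Cd8b1, whose probes disagreed in direction, differed by 0.78 and Cd3e by -0.86. Cd3d and Cd3g were not above background on any HoxA5 array. Of 1 measured B cell gene, Cd79b, the difference was 0.41.

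Vascular genes moved both ways. Of 11 endothelial genes Ly6c1 fell by 1.49 (adjusted p = 0.0483), also when adjusted over the list alone, while Emcn differed by 1.07, Flt1 by 0.89 and Vwf by 1.18 (median 0.49, camera adjusted p = 0.483). Of 10 pericyte and smooth muscle genes the contractile genes Acta2, 3.35-fold, and Tagln, 2.67-fold, rose and Vtn fell by 1.60 (adjusted p = 0.0455, 0.0318 and 0.0223). Acta2 was at 12.98 and 11.73 on the HoxA5 arrays (SD 0.89), and without HoxA5 1 it was 2.18-fold higher and did not pass. Rgs5 differed by -1.21, and 4 rose and 2 fell when adjusted over the list alone (median 0.60, camera adjusted p = 0.399). That list passed with every probe on its own (median 1.32, adjusted p = 0.0224). The 3 red blood cell genes differed by -0.95 (Hba-a1), -0.67 (Alas2) and -0.21 (Hbb-b2), none passing.

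Car9, a carbonic anhydrase induced by low oxygen, rose 5.43-fold (adjusted p = 0.0131) and was the hypoxia response gene that passed among 13. When adjusted over the list alone 4 rose and 1 fell. Ldha differed by 1.03, Pgk1, whose probes disagreed in direction, by 0.62 and Ndrg1 by -1.20. The list's median was 0.62 (camera adjusted p = 0.0187; adjusted p = 0.499 with an estimated correlation), and it did not pass where a detection p under 0.01 was asked of all arrays (adjusted p = 0.0782). Of 11 neural stem cell genes Id4, an inhibitor of helix-loop-helix factors, fell by 2.10 (adjusted p = 0.0340), also when adjusted over the list alone. Fabp7 differed by 1.36, Nes by 1.95 and Fut4 by 1.11 (median 0.18, camera adjusted p = 0.528).

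None of the lists of signalling output or oxidative phosphorylation passed, and none of their genes did in limma, over all genes or adjusted over the list alone. For receptor tyrosine kinase and MAPK output the median was 0.59 (adjusted p = 0.0547, 12 genes, 4 at an unadjusted p under 0.05), with Etv4 at 1.86, Phlda1 at 1.43, Ier3 at 1.26 and Etv1 at 0.67. It passed without mCherry 2 (adjusted p = 0.00749), without HoxA5 1 (0.0226), without mCherry 4 (0.0445), without a detection filter (0.0173), with detection p under 0.01 on all arrays (0.0465) and with every probe on its own (0.0376). Its median was 0.21 without mCherry 3. With the neuron list mean as a covariate it passed in the opposite direction (median -1.02, adjusted p = 0.0183). For Notch targets it was 0.50 (adjusted p = 0.139, 7 genes, 1 at an unadjusted p under 0.05), with Jag1 at 1.34, Notch1 at 1.18, Hey2 at 0.54 and Hes1 at 0.50. For Wnt targets it was -0.08 (adjusted p = 0.746, 6 genes, 0 at an unadjusted p under 0.05), with Lgr5 at -0.45, Nkd1 at -0.25 and Rnf43 at 0.43, and Notum not above background in HoxA5 tumours. The oxidative phosphorylation list had a median of -0.25 (adjusted p = 0.139, 17 genes, 1 at an unadjusted p under 0.05), with Cox4i1 and Uqcrc2 at -0.52, Ndufa4 at -0.43 and Ndufv1 at -0.41. It passed without background correction (adjusted p = 0.0234) and in the authors' values (adjusted p = 0.0295), and with median scaling its median was -0.047 (adjusted p = 0.465).

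The immediate early and heat shock list did not pass (median -0.29, camera adjusted p = 0.444). In limma 0 of its 12 genes passed, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. Its mean was 11.49 on mCherry 2 and between 8.53 and 9.34 on the other arrays. Dusp1 differed by -1.62, Fosb by -2.36, Dnajb1 by -0.61 and Egr2 by 1.03. Of 38 other Hox genes on the fixed list 2 were measured, Hoxa13 with a difference of 0.31 and Hoxc10 with -0.09, and neither passed. The Y-linked genes differed by 0.07 (Uty), 0.44 (Eif2s3y) and 0.16 (Kdm5d), with both sexes in each group.

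**Figure D2:**
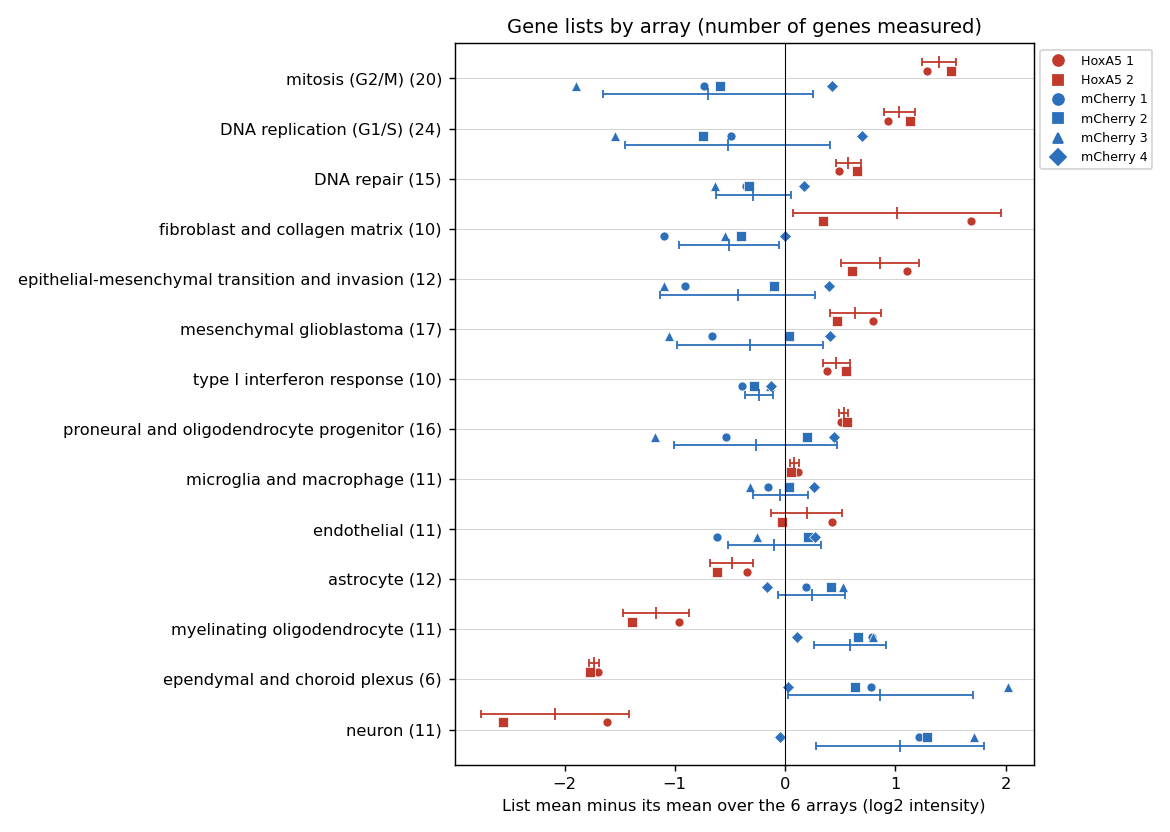
Mean log2 intensity of 14 gene lists on each array minus the list's mean over the 6 arrays (horizontal axis), with the number of measured genes after each name; points are arrays, red for HoxA5 and blue for mCherry tumours, and bars give the mean and SD of each group (n = 2 and n = 4). The mCherry 4 array has the lowest neuron list mean of the mCherry arrays (10.53) and the highest mitosis list mean (8.56).

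Counting lists, 15 of 26 passed, 10 higher and 5 lower in HoxA5 tumours. None passed with an estimated correlation, where 2 lists had an unadjusted p under 0.05, and 4 passed in fry, those of neurons, myelin, ependyma and choroid plexus, and type I interferon response. Without background correction 7 of the 15 medians were over 1.5 times smaller, and all 15 lists passed. With the neuron list mean as a covariate, 8 lists passed, 4 of them among the 15. These were fibroblast and collagen matrix in the same direction and mitosis, DNA replication and proneural in the opposite one. The other 4 had not passed without it. They were microglia and macrophage (median -0.33), receptor tyrosine kinase and MAPK output (-1.02) and Notch targets (-1.001), all lower, and Wnt targets (0.87), higher. With it the medians of 16 lists changed sign, among them DNA repair (-0.23), mesenchymal (-0.78), monocyte and neutrophil (-0.69), astrocyte (0.32) and ependymal and choroid plexus (0.20), which no longer passed. Without a change of sign, the neuron (-0.29), myelin (-0.37), transition and invasion (0.054), interferon (0.42), antigen presentation (-0.51) and hypoxia (0.38) lists no longer passed either. With it 0 genes passed in either direction in limma, with 153 higher and 178 lower at an unadjusted p under 0.05. The differences of 57 of 134 named genes changed sign with it. The neuron list means of the groups do not overlap (8.02 and 8.97 against 10.53 to 12.29).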

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

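Among 160 genes and list means examined over the 4 mCherry tumours, 4 had a tumour far from the others relative to the group's range. That is a smaller share than the 1 in 20 or so that chance alone gives, so the number of flags shows nothing beyond chance. Brca2 was at 7.18 on mCherry 4 and between 6.65 and 6.67 on the other mCherry arrays, a gap of 0.970 of the group's range. Mgmt was at 7.05 on mCherry 4 and between 6.81 and 6.84 on the others, a gap of 0.876 of the range. Hoxa13 was at 5.16 on mCherry 3 and between 6.22 and 6.43 on the others, a gap of 0.837 of the range. Fosb, an immediate early transcription factor, was at 12.45 on mCherry 2 and between 5.99 and 6.98 on the others, a gap of 0.847 of the range. Among detected probes without a gene name, which entered no comparison of genes, 74 of 3641 passed the same threshold, 10 higher and 64 lower in HoxA5 tumours.

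Other genes induced by neuronal activity were high on the same array as Fosb. On mCherry 2, Npas4 exceeded the highest other mCherry array by 5.15 on the log2 scale, Arc by 3.88, Egr4 by 2.96 and Fos by 2.01. Egr1 (0.81) and Egr2 (0.12) exceeded it least. The median was 2.49 over 8 rapid genes, which include Fosb itself, the gene that prompted the comparison. The comparison with neuron content was chosen after these values had been seen, and that with late genes before its own result. More neurons in the piece are argued against, because the neuron list lay below the highest other mCherry array by a median of -0.50 (SD over members 0.58). Genes listed as late activity-regulated exceeded that array by a median of 1.15, in 7 of 8 genes, with Bdnf at 2.73. Activation of neurons before the tissue was taken may therefore account for the pattern. When each of these genes rises was not measured, so the list does not date the activation. The labels list seizure among the signs of illness, without saying in which mouse. Stress of the tissue before or during collection stays open, since Hspa1a (4.64) and Atf3 (4.19) were also above the other mCherry arrays, and no group of the design bears on it.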

How the results depend on the processing

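Sex as a block and the neuron list mean as a covariate were chosen after the data had been seen. Over 19 alternatives for 134 genes, single genes kept direction and side of the threshold in 2046 of 2484 cases, lost a call in 268, gained one in 94 and reversed in 76. Over 21 alternatives for 26 lists, these were 461, 41, 15 and 26 of 543 cases, a changed sign counting as reversed for genes and lists alike. The other variance models do not enter camera, so their list cases were the same by construction. The estimated correlation, fry and the sex block leave the medians as they are, so no list could reverse there. The tally of lists therefore overstates their stability. Of the 134 genes 52 were called in the main fit, and the others could count as kept by staying uncalled. Of the 52, 30 no longer passed without mCherry 1 and all 52 with the neuron covariate, against 0 without mCherry 4 or with array weights. Against 148 higher and 568 lower genes, 349 were lower without background correction, 265 higher with median scaling and 362 lower in the authors' values. Without a detection filter 95 were higher, and 94 with detection p under 0.01 on all arrays. Array weights gave 642 higher and 1104 lower, an adjusted p under 0.1 gave 506 and 1003, and the sex block 31 and 307. Each group was evenly split by sex, so that block leaves differences as they are and takes up 1 degree of freedom. The cause of the other changes was not tested.

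With the replicate number as a block, 236 genes were higher, of which 83 were among the 148, and 669 lower, of which 490 were among the 568. The numbers do not pair the samples. An mCherry array whose number no HoxA5 array shares is fitted exactly and adds nothing to the group difference. Under this block that difference therefore rests on HoxA5 1 and HoxA5 2 against mCherry 1 and mCherry 2 only. Deviations of equally numbered tumours correlated across genes at -0.364 and -0.236. Under this block Uty was at -0.15, Eif2s3y at -2.12 and Kdm5d at -0.87. The mean of a gene's probes put Cd8b1 at -0.13, and array weights put Eif2s3y at -0.16 and Kdm5d at -0.045. Under the replicate block the immediate early and heat shock list passed (median -0.87, adjusted p = 0.0182) and the antigen presentation list did not (adjusted p = 0.207). The mean of the immediate early and heat shock list was highest on mCherry 2 (11.49), which counts for more under this block than in the main fit. The Wnt targets median was 0.020 with median scaling and 0.029 without a detection filter, and that of pericytes and smooth muscle was -0.027 without that filter. With detection p under 0.01 on all arrays, medians were 0.13 for T and NK cells, -0.12 for pericytes and smooth muscle and 0.059 for immediate early and heat shock genes.

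Leaving out 1 array gave 0 to 1038 higher and 2 to 1370 lower genes. The fits with 1 HoxA5 array assume that it varies as the mCherry arrays do. Over these fits Hoxc10 ran from -0.34 to 0.17, Cd79b from -0.098 to 0.90, Uty from -0.17 to 0.31, Eif2s3y from -2.72 to 3.58, Kdm5d from -0.96 to 1.28, Nkd1 from -0.50 to 0.0015 and Hbb-b2 from -0.64 to 0.22. Medians ran from -0.54 to 0.31 for the immediate early and heat shock list and from -0.50 to 0.15 for Wnt targets. Of 26 lists, 15 passed, 0 with an estimated correlation, 4 in fry and 8 with the neuron covariate, 3 of these reversed and 4 not among the 15.

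With the neuron list mean as a covariate, 0 genes were higher and 0 lower in limma, with 153 and 178 at an unadjusted p under 0.05. The covariate is measured on the same arrays and does not overlap between the groups, so the group difference is an extrapolation with few degrees of freedom. The following reversed. Lists past the threshold with and without it were mitosis at -1.15, DNA replication at -1.80 and proneural and oligodendrocyte progenitor at -1.26. Lists past it only with the covariate were microglia and macrophage at -0.33, receptor tyrosine kinase and MAPK output at -1.02, Notch targets at -1.001 and Wnt targets at 0.87. Lists not past it with the covariate were DNA repair at -0.23, neural stem cell at -0.46, mesenchymal at -0.78, astrocyte at 0.32, ependymal and choroid plexus at 0.20, monocyte and neutrophil at -0.69, T and NK cell at 0.54, endothelial at -0.073 and pericyte and smooth muscle at -0.43. Genes turned negative were Cdkn2a -1.65, Aldh1a3 -1.59, Bub1b -1.10, Tecta -0.56, Kif11 -1.15, Aurka -1.11, Pcna -0.66, Fen1 -0.060, Rrm1 -1.16, Pole -1.20, Fanci -0.30, Hoxa13 -1.14, Sox11 -1.25, Lhfpl3 -1.69, Dll3 -0.73, Fut4 -0.60, Nes -1.12, Fabp7 -2.52, Cd44 -1.39, Runx1 -0.58, C1qb -0.073, C1qc -0.33, Vcan -0.62, S100a8 -1.01, Emcn -0.99, Ldha -0.36, Phlda1 -1.80, Ier3 -0.70, Etv4 -1.04, Egr2 -1.97, Jag1 -0.27, Notch1 -1.20, Hey2 -0.50, Hes1 -1.29, Mmp14 -0.87 and Twist1 -0.11. Genes turned positive were Scn4b 0.33, Tac1 2.41, Sesn1 0.16, Gjb6 0.33, Gja1 0.23, Aldoc 0.31, Kl 0.78, Folr1 1.46, Ly6c1 0.41, Igf2 0.0072, Hba-a1 2.38, Alas2 2.07, Hbb-b2 2.84, Ndrg1 0.44, Fosb 0.82, Dnajb1 0.11, Notum 1.06, Lgr5 1.48, Nkd1 1.53, Cox4i1 0.12 and Ndufv1 0.11. The chip as a block was not run. Signal over background limits dim genes such as Ttk, Ube2c and Ccna2, whose folds are bounds.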

Other observations

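Gene families were also grouped by symbol after the data had been seen. They share genes with the lists, such as Syt1 and the type I collagen chains, and are no independent support. The 6 described here are part of those tested. GABA receptor, calcium channel, histone and metalloproteinase families also passed in camera. Those of kinesins, proteasome, chaperonins with heat shock proteins, and aldehyde dehydrogenases did not. Of 62 potassium channel genes 9 fell in HoxA5 tumours, among them Kcnc1, Kcnab1 and Kcnj4, with a median difference of -0.69 (camera adjusted p = 2.10e-06; adjusted p = 0.338 with an estimated correlation). Of 13 synaptotagmins 5 fell (median -0.66, adjusted p = 1.41e-05; 0.338 with an estimated correlation), as did Gria1 and Grin2b of 14 ionotropic glutamate receptor genes (median -0.52, adjusted p = 0.0222; 0.383 with an estimated correlation). Of 30 collagen genes 4 rose, Col11a1 and Col5a2 beside the type I chains (median 1.33, adjusted p = 7.82e-05; 0.383 with an estimated correlation). Ncapg rose among 19 minichromosome maintenance and condensin genes (median 1.45, adjusted p = 1.05e-05; 0.383 with an estimated correlation). Of 49 ribosomal protein genes Rps15a fell, and the family did not pass (median 0.26, adjusted p = 0.0644). These members were named after their values were seen, and the sizes of the 6 medians depend on the processing. In the same order they were -0.24, -0.41, -0.31, 0.43, 0.74 and 0.26 without background correction, and -0.64, -0.53, -0.39, 1.44, 1.58 and 0.43 with median scaling.

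All tests of explanations in this part except that of other splits of the arrays were chosen after the results had been seen. Neuronal and myelin genes were lower and mitotic genes higher in HoxA5 tumours, and mCherry 4 lay between the groups in both. An even loss of every non-tumour cell type from the HoxA5 pieces is argued against, because the microglia and macrophage median lay above the neuron median by 3.46, more than the lists' summed SDs of 1.10, although a gain of microglia beside it stays open. More surrounding brain in the mCherry pieces may account for the fall of neuropeptide and monoamine genes listed as region-restricted. Their median difference was -2.77 (SD over members 1.38), negative in 17 of 18, with Oxt at -3.94, Sst at -3.97 and Tph2 at 0.71. Of the 18, 5 passed and 4 were at background on both HoxA5 arrays. Over the 14 detected on a HoxA5 array the median was -2.89 (SD 1.37), negative in 13. These genes are themselves neuronal, so they cannot tell more surrounding brain from fewer neurons within the tumour. Whether less dilution by brain also accounts for the mitotic genes cannot be told apart from a difference in division. On the linear scale the mCherry trend was exceeded 1.79-fold, with both HoxA5 arrays above its 95% interval (DNA replication genes were at 1.01 and 1.09 times theirs). That trend rests on 4 arrays and is carried beyond their neuron levels. On the log2 scale, added after that result, the HoxA5 arrays lay below the trend by a mean of -1.54 and inside its interval. That interval ran from 6.14 to 14.90 for HoxA5 1 and from 6.00 to 17.25 for HoxA5 2. It is too wide for an excess to show, so the log2 scale decides nothing. Faster growth or invasion of HoxA5 tumours, a biological difference that would change the same tissue shares, stays open as untested.

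The loss of Ttr was the largest single difference. A fault of its probe as the only source of the fall is argued against, since 12 of 13 other choroid plexus genes had both HoxA5 arrays below every mCherry array. Among them were all 8 that were detected on a HoxA5 array. Over all genes, 35.5% did not overlap in either direction, and 5 of the 13 genes passed. The size of the fall in Ttr itself rests on a single probe. Choroid plexus in the mCherry pieces may account for it, with a median difference of -2.17 (SD over members 0.89) over those 13 genes and -2.06 (SD 1.01) over the 8 detected, among them Slc5a5 at -3.28 and Slc13a4 at -3.23, while 5, such as Otx2 (at least 4.19-fold lower), were at background on both HoxA5 arrays. Clic6, Kl and Folr1 of these genes are also on the fixed ependymal and choroid plexus list, whose other members Aqp1 (1.08) and Foxj1 (0.24) went the other way, and with these 2 the count was 12 of 15 and the median -1.78 (SD over members 1.30). How the tumours were cut from the brain is not given in the sources used here, and an effect of HoxA5 on choroid plexus or on tumour position was not tested.

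Of the 15 splits of the 6 arrays into 2 and 4, 1 gave as many called genes as the real one, which is the real split itself with 716, and the highest other gave 1. With 15 splits no share under 0.05 can be reached. Each other split mixes HoxA5 and mCherry arrays, so a real group difference widens its spread and lowers its count. The contrast of 716 with 1 is therefore no measure of chance.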
